A study of Danio rerio with 35 samples.

How the data were processed

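Polyadenylated RNA of whole hearts from adult zebrafish was profiled in 8 libraries, 4 from WT fish and 4 from fish overexpressing klf1, and groups were taken from the genotype in the sample labels. Per the labels' protocols, RNA was purified with Qiagen miRNeasy kits and libraries were made with Kapa stranded mRNA kits. The values used are the authors' raw counts, deposited as whole numbers per gene and library with no normalization and no pooling of replicates, per the file headers and the values. The submitters' processing notes name the genome build danRer10 and the tools Bowtie2 2.2.8 and deepTools 3.1.2 for all samples of the series, without their roles. The RNA aligner, the counting tool, the gene annotation and the strand setting are not given in the sources used here. Whether reads of near-identical paralogs or of overlapping genes were split, dropped or counted more than once is therefore unknown, and such genes are reported as uncertain. No genome of the build used was at hand, so no coordinates are given. Gene symbols are those of the count table. Of the symbols in the files of single libraries, 11 were written as dates, as spreadsheet programs do. The names were taken from the joint table, of which 8 of 8 libraries equalled a column. The other 27 of the 35 samples were not analysed here.

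Library totals ranged from 9829896 to 13083853 counts over 14781 genes. Pairs of libraries of a genotype differed by more than sampling noise (chi-square per degree of freedom 7.77 to 56.6 over genes with counts), so none was treated as the same library sequenced again. Spearman correlations of log2 CPM across genes, which are not independent replicates, were at least 0.972 within and at most 0.863 between genotypes. The labels give no batch, date, sex or clutch, so such effects could not be separated from genotype.

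Counts were analysed in R 4.3.3. Genes were kept by edgeR's filterByExpr with the genotype as group (10493 genes), scaled with TMM factors, and tested with edgeR 4.0.16's quasi-likelihood F-test (glmQLFit with robust estimation, glmQLFTest, two-sided) with an intercept and genotype. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. TMM factors lay between 0.75 and 0.83 in WT and between 1.226 and 1.317 in klf1 libraries. Every log2 fold change is klf1 minus WT from this model. Its standard error was taken as the fold change divided by the square root of the F statistic, which is approximate. CPM values are scaled by TMM and given as mean ± SD over 4 libraries. For klf1 an exact two-sided permutation test of log2 CPM over the 70 assignments of 4 against 4 was added. The floor of 3 counts was converted to CPM per library.

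Before the data were examined, 27 gene lists were fixed from textbook knowledge of the zebrafish heart, with 859 genes, of which 718 had a symbol in the count table. They cover muscle and metabolism, cell cycle and signalling, the other cell types a heart can hold, and tissues outside it; 8 genes are in more than 1 list. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the 27 lists. Camera with an estimated correlation and fry were alternatives. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. A further 13 lists built from symbol patterns, such as genes starting with mrpl or mrps, were chosen after the fixed lists were seen. The patterns for the proteasome and for DNA repair were narrowed after their values were seen, to drop psmc3ip and xrcc6bp1, which belong to neither. From 6 of these lists 15 further symbols that match a pattern but name other proteins, such as co-repressors that bind irf2 in the interferon list, were left out after their values were seen, and the 13 lists were tested again. The calls were the same with them.

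The genes named in the text follow a rule also fixed before the data were examined. It takes klf1, the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between genotypes, up to 4 members per list with the smallest adjusted p, and up to 2 per list with the highest expression. Further genes were named after their values were seen. These are members that make up a count of 5 or fewer in a list, such as vmhc, csrp3, camk2d1, atp2a2b, fxyd1, cox8a, cpt1aa, ccnf, gapdhs, eno1b, pfkfb3, tbx3a and hmbsb, members listed at 0 such as runx1, and examples from the 13 added lists. Some single genes are not reported here.

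Alternatives fixed before the data were examined were the scaling (DESeq2 size factors, upper-quartile factors, library totals, and factors without erythroid and the 50 most counted genes), the filter (none, or at least 50 counts in at least 4 libraries), and the test (DESeq2 1.42.0, limma-voom, edgeR without robust estimation). They further included counts thinned to the smallest library, a threshold of 0.01, 1 surrogate variable from sva 3.50.0, and each library left out in turn. Chosen after seeing the data were a test against an absolute log2 fold change of 1 (glmTreat), leaving out WT library 3 and klf1 library 1 together, and lists without shared genes. The pipeline was tested on simulated data: counts drawn from the WT means and library sizes for 10493 genes, with 4 libraries per group and 100 genes changed by each of 2 sizes. At an adjusted p under 0.05 edgeR recovered 73% of genes changed by log2 1 and 92% of those changed by log2 2, and called 17 unchanged genes. With the 60 most abundant genes lowered by log2 2, the median log2 fold change of unchanged genes was 0.01 with TMM and 0.56 with library totals. Camera recovered 5 of 5 raised lists and called 0 of 25 unchanged lists with either correlation. In that simulation genes varied independently, so it does not test how camera treats genes that vary together. All simulations changed far fewer genes than were called in the data. They therefore do not give the share of genes recovered in this comparison, nor test TMM scaling where most genes change.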

Results

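Messenger RNA of whole adult zebrafish hearts was sequenced in 2 genotypes, wild type (WT) and klf1 overexpressing, with 4 libraries each. Klf1 is a zinc-finger transcription factor of the Krüppel-like family, known from red blood cell development. The title of the series names the question as whether Klf1 brings about renewal of cardiomyocytes in the adult heart, and the RNA comparison asks which transcripts differ in hearts that overexpress it. The labels do not say how klf1 was overexpressed, in which cells or for how long. The other 27 of the 35 samples, which profile DNA methylation, open chromatin, histone marks and tagged protein binding in the same 2 genotypes, were not analysed here. Each RNA library held between 9829896 and 13083853 gene counts. The WT libraries 1 to 4 held 11483636, 10109846, 11064195 and 9829896 counts, and the klf1 libraries 1 to 4 held 11065768, 11705960, 11007427 and 13083853. Of 14781 genes listed, 1086 were at 0 in all 8 libraries and 10493 had enough counts to test. At these depths a count of 3, the upper limit that a count of 0 allows, corresponds to between 0.179 and 0.378 CPM after TMM scaling, 0.345 or more in each WT library. This limit covers counting error only. The labels do not say that the libraries of a genotype came from separate animals. The p-values set the genotype difference against the spread between libraries of a genotype, and that spread may be technical.

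The overexpressed gene was read first. klf1 stood at 216 ± 78.9 CPM in WT hearts and 646 ± 63.7 CPM in klf1 hearts (SD, n = 4), a 2.99-fold difference with a log2 fold change of 1.58 ± 0.24 (SE) and an edgeR adjusted p of 0.000126. The 4 WT libraries read 174, 268, 296 and 128 CPM and the 4 klf1 libraries 595, 655, 733 and 602 CPM. The groups did not overlap (exact permutation test over 70 assignments, two-sided p = 0.0286, the smallest this design allows). Scaled by library totals alone, the log2 fold change was 2.31.

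The genotypes differed across most of the measured transcriptome, and the transcripts that dominate a normal heart lost much of their share. The 10 genes with the most counts over all libraries took 26.1 ± 0.899% of counts in WT hearts and 8.07 ± 1.42% in klf1 hearts (SD, n = 4). The 10 most counted genes of each library itself took 26.7 ± 1.06% and 9.49 ± 0.865%. The ventricular myosin heavy chain vmhcl alone took 8.81 ± 0.813% in WT and 2.6 ± 0.696% in klf1. With edgeR's quasi-likelihood test at an adjusted p under 0.05, 3377 genes were higher and 3084 lower in klf1 hearts, 6461 or 61.6% of those tested. Of these, 1884 of the higher and 1614 of the lower genes differed by a log2 fold change of 1 or more. The WT and klf1 libraries did not overlap for 5983 tested genes (57%), against 2.86% by chance. The first principal component held 85.7% of the variance and separated the genotypes. The split between higher and lower genes depended on the scaling: 52.3% of called genes were higher with TMM factors and 83% with library totals alone (6836 higher, 1398 lower). The median log2 fold change of all tested genes was 0.03 with TMM, 0.01 with DESeq2 size factors, 0.11 with upper-quartile factors and 0.75 with library totals. Changes are given from the fit with TMM factors.

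**Figure D1:**
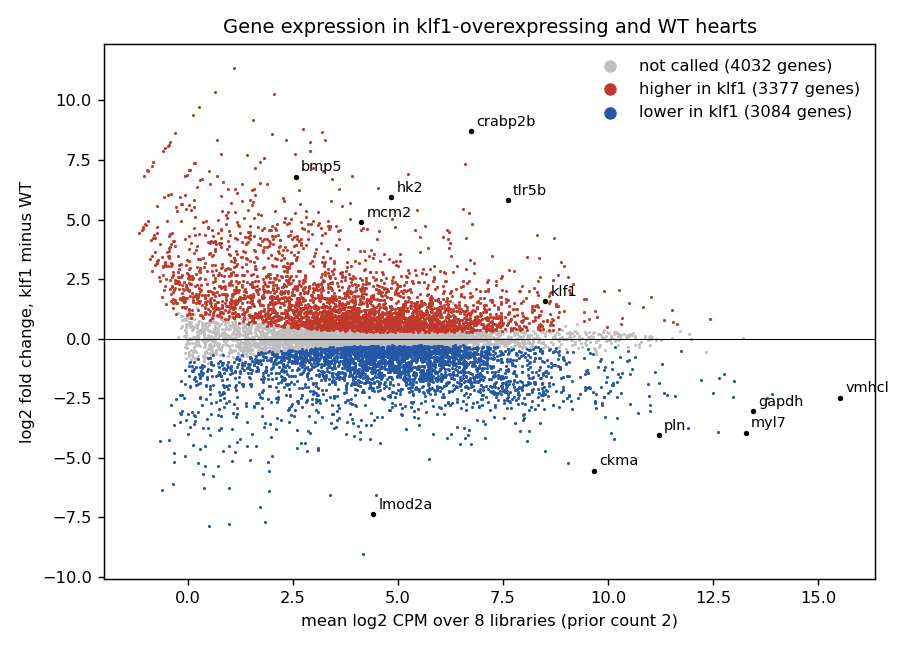
Each point is 1 of the 10493 tested genes, with its mean log2 CPM over the 8 libraries on the horizontal axis and its log2 fold change (klf1 minus WT) on the vertical axis. Red and blue points are the 3377 higher and 3084 lower genes at an edgeR adjusted p under 0.05, and grey points were not called. Many of the most expressed genes, among them vmhcl, myl7 and gapdh, lie below 0, while klf1, tlr5b, hk2 and crabp2b lie above it.

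Among genes with a mean log2 CPM of at least 3 and no overlap between groups, the steepest rises were led by crabp2b, a cellular retinoic acid binding protein, which went from 5.45 ± 3.55 to 2290 ± 278 CPM (SD, n = 4; log2 fold change 8.71 ± 0.42 SE, edgeR adjusted p = 2.57e-08). tlr5b, a receptor for bacterial flagellin, rose from 26.5 ± 6.18 to 1480 ± 253 CPM (5.8 ± 0.24), and hk2, a hexokinase that starts glycolysis, from 3.81 ± 2.2 to 235 ± 47.7 CPM (5.93 ± 0.34). The phospholipid transfer protein pltp rose by 6.91 ± 0.33, the membrane repair protein myof by 6.32 ± 0.19, and the glutathione peroxidase family member gpx7 by 7.04 ± 0.39. Both cpo (8.67 ± 0.27) and nrn1a (8.35 ± 0.35) rose from WT levels of 0.393 and 0.482 CPM, close to the limit that a count of 0 allows, so these fold changes are imprecise. The steepest fall was that of zgc:112242, from 431 ± 258 to 0.796 ± 0.659 CPM. lmod2a, a leiomodin of the sarcomere's thin filament, fell from 309 ± 33.2 to 1.83 ± 2.03 CPM (log2 fold change -7.38 ± 0.55), and ckma, a muscle creatine kinase, from 5670 ± 621 to 121 ± 35 CPM (-5.54 ± 0.26). The sodium pump subunit atp1a3b fell from 3750 ± 806 to 102 ± 103 CPM (-5.2 ± 0.63). The creatine synthesis gene gamt changed by -5.04 ± 0.22, the acyl-CoA synthetase acsl1b by -4.71 ± 0.41, and the muscle ubiquitin ligase trim63a by -4.44 ± 0.24. Leaving out klf1 library 2 moved the log2 fold changes of zgc:112242, lmod2a and atp1a3b to -9.82, -8.54 and -6.22.

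Gene lists fixed in advance describe the rest. Of 27 lists, 15 differed from the other tested genes by limma's camera with a preset correlation of 0.01 (7 higher, 8 lower). None was called when the correlation was estimated per list (camera, 0 lists at an adjusted p under 0.05, 6 at an unadjusted p under 0.05), while the rotation test fry called 22 (14 higher, 8 lower). The counts of members below are from edgeR over all genes tested; adjusted over the list alone they were identical except for the cardiac transcription factor, Hippo-Yap and erythroid lists. Some smaller falls given below lost their call with library totals, the setting that puts the median gene at 0.75. They were prps1a (log2 fold change -0.05 there), slc38a2 (-0.45), desma (-0.18), dusp6 (-0.29), pecam1 (-0.14), klf15 (-0.22), acta1b (-0.35), kdm6bb (-0.07), f3b (-0.2), sema3d (-0.14), nop14 (-0.05) and ahsg1 (-0.86). Of genes given below as not called, atp2a2b (0.87), cpt1aa (0.74) and atf4a (0.96) were called higher with library totals.

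**Figure D2:**
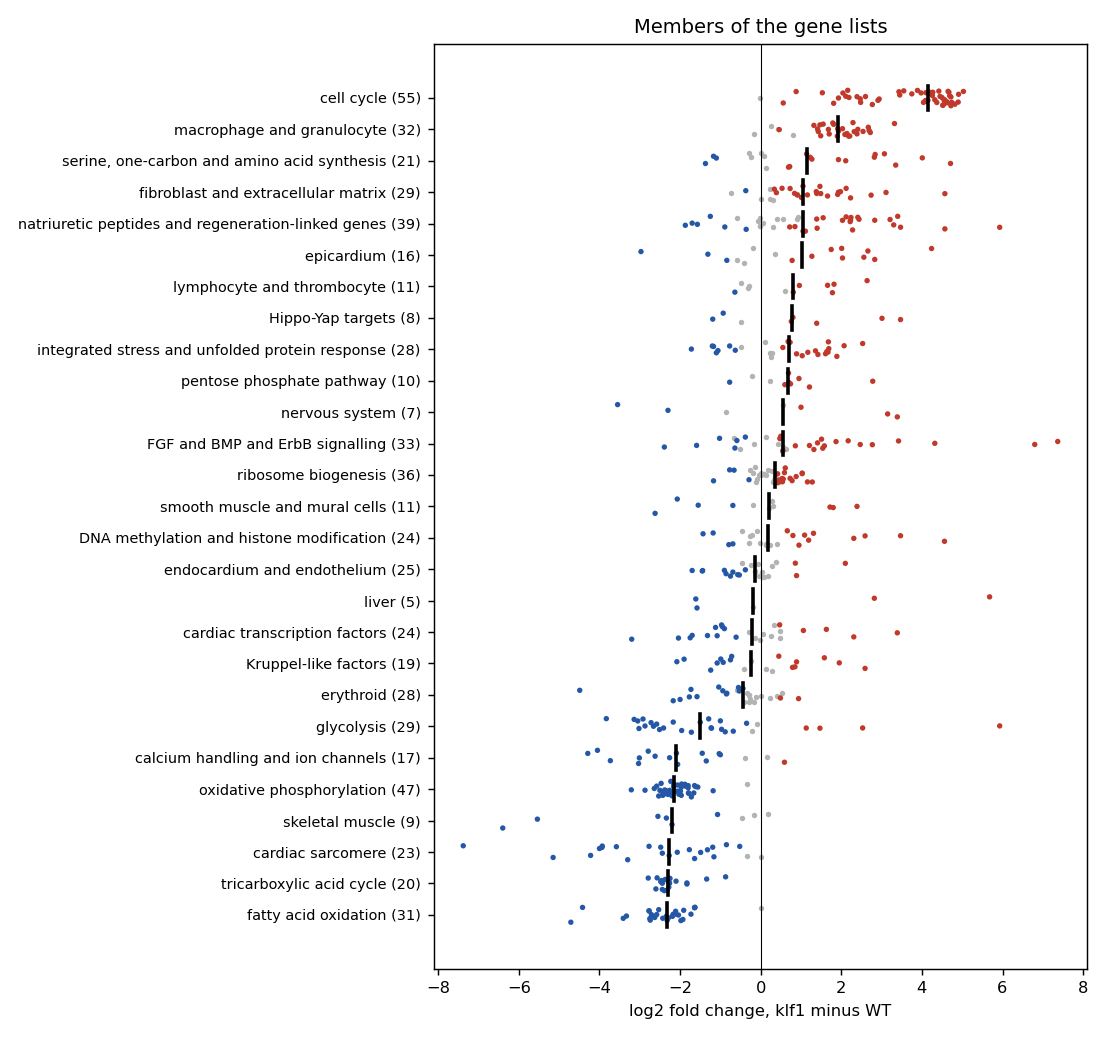
Each point is a tested member of a gene list, at its log2 fold change (klf1 minus WT) on the horizontal axis. Lists are in rows with the number of tested members in brackets, black bars are list medians, and red, blue and grey points are members called higher, called lower or not called by edgeR. The cell cycle list has the highest median (4.15) and the fatty acid oxidation list the lowest (-2.32).

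The contractile machinery of cardiac muscle fell. Of 23 tested genes of the cardiac sarcomere, 21 were lower and 0 higher in klf1 hearts (edgeR adjusted p under 0.05; 0 higher also at an adjustment over the list alone), and the median log2 fold change was -2.27, or 4.84-fold lower. The atrial and ventricular light chain myl7 fell from 40100 ± 8490 to 2610 ± 941 CPM (SD, n = 4; log2 fold change -3.94 ± 0.31 SE), the cardiac actin actc1a from 24900 ± 3940 to 1640 ± 500 CPM (-3.93 ± 0.27), and vmhcl from 113000 ± 10600 to 20300 ± 5390 CPM (-2.48 ± 0.24). The Z-disc protein ldb3a changed by -3.58 ± 0.27. Outside the calls stood vmhc, a close copy of vmhcl, at 969 ± 280 and 981 ± 241 CPM, and csrp3, at 1000 ± 187 and 792 ± 171 CPM (adjusted p = 0.157; 0.0357 without klf1 library 1, 0.0365 without both it and WT library 3). Reads of vmhc and vmhcl could be split between the copies, so both values are uncertain. vmhc was called higher with library totals (log2 fold change 0.73). In the same libraries the median of the macrophage and granulocyte list was 1.91 and that of the endothelial list -0.15. The camera adjusted p of the sarcomere list was 1.42e-09, and the adjusted p was 0.218 with an estimated correlation.

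Calcium handling and membrane excitability genes fell alongside. Of 17 tested, 14 were lower and 1 higher, with a median of -2.09 (camera adjusted p = 1.19e-06; adjusted p = 0.245 with an estimated correlation). The sarcoplasmic calcium pump atp2a2a fell from 14500 ± 3510 to 1100 ± 384 CPM (SD, n = 4; log2 fold change -3.73 ± 0.29 SE), its inhibitor phospholamban (pln) from 9890 ± 639 to 596 ± 252 CPM (-4.05 ± 0.3), and calsequestrin (casq2), the calcium buffer of the store, from 1230 ± 114 to 62.8 ± 22.6 CPM (-4.29 ± 0.26). The paralog atp2a2b read 65.5 ± 19.1 and 72.7 ± 12.3 CPM and the sodium pump regulator fxyd1 725 ± 129 and 556 ± 93.6 CPM, neither called (fxyd1 was called lower by DESeq2, log2 fold change -0.39). The 1 higher member, the kinase gene camk2d1, differed by 0.59 ± 0.2. Its call was lost without WT library 1 (0.52, adjusted p = 0.0654), WT library 2 (0.49, 0.0695) or klf1 library 1 (0.52, 0.0558). A list of skeletal muscle genes, included as a marker of other muscle, had 6 of 9 tested members lower and 0 higher (median -2.2, camera adjusted p = 0.00304; adjusted p = 0.218 with an estimated correlation). Among them were ckma and ckmb, creatine kinases that heart muscle also uses, the calcium buffer casq1b (-2.2 ± 0.18) and the actin acta1b (-1.07 ± 0.18).

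The genes of mitochondrial energy production were lower almost without exception. Of 47 tested oxidative phosphorylation genes, 46 were lower and 0 higher (median log2 fold change -2.16; camera adjusted p = 2.64e-18; adjusted p = 0.275 with an estimated correlation). All 20 tested genes of the tricarboxylic acid cycle were lower (median -2.3; 1.09e-10; adjusted p = 0.245 with an estimated correlation). Of 31 tested fatty acid oxidation genes, 30 were lower and 0 higher (median -2.32; 3.36e-14; adjusted p = 0.218 with an estimated correlation). The succinate dehydrogenase subunit sdha fell from 1250 ± 204 to 171 ± 35.9 CPM (SD, n = 4; 7.31-fold), the ATP synthase subunit atp5b from 6280 ± 671 to 1200 ± 302 CPM (5.21-fold) and the malate dehydrogenase mdh2 from 5810 ± 964 to 1190 ± 289 CPM (4.88-fold). cpt1b, which commits long-chain fatty acids to mitochondrial import, fell from 202 ± 22.2 to 30.9 ± 6.37 CPM (6.53-fold), acadvl from 3870 ± 762 to 384 ± 101 CPM (10.1-fold) and the fatty acid carrier fabp3 from 2380 ± 620 to 520 ± 244 CPM (4.57-fold). The members not called were cpt1aa (17.2 ± 1.19 and 17.4 ± 0.64 CPM) and cox8a (110 ± 9.77 and 87.3 ± 20.3 CPM). cox8a was called lower without klf1 library 1 (log2 fold change -0.52), without both it and WT library 3 (-0.49) and with 1 surrogate variable (-0.33), and called higher with library totals (0.37, adjusted p = 0.0324 by edgeR).

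Most glycolytic genes fell. Of 29 tested, 23 were lower and 4 higher (median -1.5; camera adjusted p = 1e-05; adjusted p = 0.218 with an estimated correlation). Most of the abundant forms fell: gapdh from 33700 ± 7470 to 4080 ± 1790 CPM (SD, n = 4; log2 fold change -3.05 ± 0.33 SE), the enolase eno3 from 5040 ± 907 to 573 ± 160 CPM (-3.14 ± 0.24), the phosphoglycerate mutase pgam2 from 789 ± 146 to 108 ± 20.4 CPM and the lactate dehydrogenase ldhba from 5900 ± 1130 to 727 ± 147 CPM. The 4 that rose were hk2, the enolase eno1b (2.53 ± 0.22), pfkfb3, whose product activates phosphofructokinase (1.47 ± 0.17), and gapdhs (1.13 ± 0.15), which went from 312 ± 22.3 to 683 ± 105 CPM. The pentose phosphate list, a source of NADPH and ribose, had 7 of 10 tested members higher and 1 lower, prps1a (-0.77 ± 0.12). Its median was 0.69 and its camera adjusted p 0.0693, or 0.0342 with the stricter filter on counts. Here pgm2 rose by 2.78 ± 0.17, pgd by 1.21 ± 0.15 and taldo1 by 0.7 ± 0.12.

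Genes for serine, one-carbon and amino acid synthesis rose as a list, with 13 of 21 tested members higher and 3 lower (median 1.14; camera adjusted p = 0.0171; adjusted p = 0.218 with an estimated correlation; 0.109 with library totals). psat1, the aminotransferase of serine synthesis, rose from 9.9 ± 2.13 to 259 ± 72 CPM (SD, n = 4; log2 fold change 4.71 ± 0.24 SE), shmt1, which passes serine carbon to folate, by 2.82 ± 0.16, and the cystathionine synthases cbsa and cbsb by 2.11 ± 0.16 and 3.35 ± 0.27. The 3 lower members were the mitochondrial folate enzyme mthfd2 (-1.37 ± 0.17) and the amino acid transport genes slc3a2b (-1.1 ± 0.15) and slc38a2 (-1.17 ± 0.21).

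The cell cycle list rose further than any other fixed list. Of 55 tested members, 54 were higher and 0 lower, with a median log2 fold change of 4.15, or 17.7-fold (camera adjusted p = 1.53e-20; adjusted p = 0.218 with an estimated correlation). The replication helicase subunit mcm2 rose from 3.12 ± 0.383 to 93.4 ± 19.3 CPM (SD, n = 4; log2 fold change 4.9 ± 0.2 SE), the polymerase clamp pcna from 36.6 ± 12.1 to 275 ± 70.6 CPM (2.91 ± 0.25) and the ribonucleotide reductase subunit rrm2 from 10.6 ± 2.82 to 203 ± 15.6 CPM (4.26 ± 0.19). Cyclin A2 (ccna2) rose by 4.61 ± 0.21, the cohesion factor esco2 by 4.52 ± 0.2 and cyclin D1 (ccnd1) by 1.93 ± 0.14. The exception was ccnf, at 18.2 ± 7.77 and 18.1 ± 2.88 CPM, which was called higher with library totals (0.72, adjusted p = 0.0288 by edgeR). In the same libraries 28 of 32 tested macrophage and granulocyte genes were higher, with a median of 1.91.

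**Figure D3:**
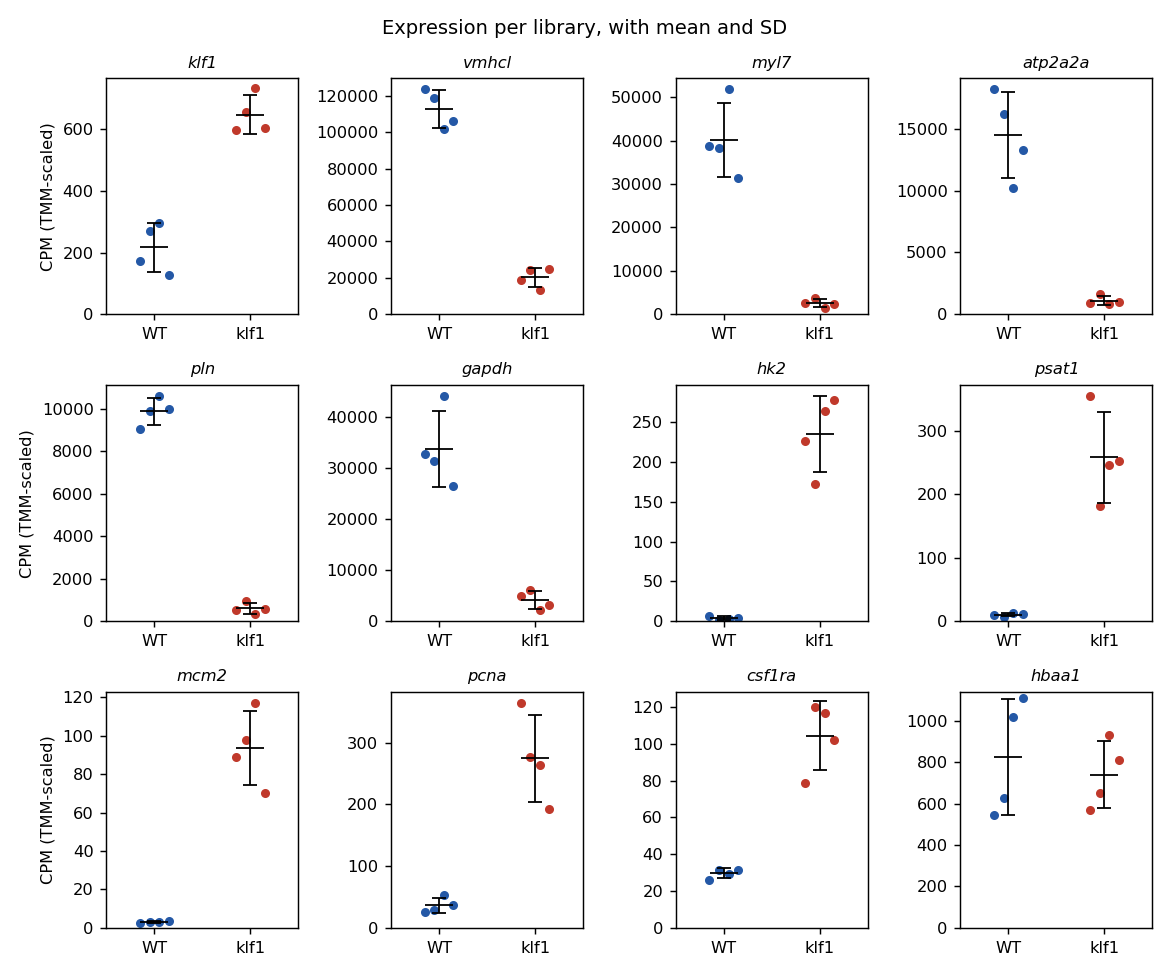
CPM after TMM scaling on a linear vertical axis from 0 for 12 genes, with each of the 4 WT libraries in blue, each of the 4 klf1 libraries in red, the mean as a black bar and the SD as whiskers. klf1, hk2, psat1, mcm2, pcna and csf1ra are higher and vmhcl, myl7, atp2a2a, pln and gapdh lower in every klf1 library, while the WT and klf1 libraries overlap for the globin gene hbaa1.

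Cardiac transcription factors went both ways. Of 24 tested, 5 were higher (6 adjusted over the list alone) and 11 lower, with a median of -0.21 that became 0.5 with library totals. The list was not called (camera adjusted p = 0.236). tbx5a fell from 188 ± 32.9 to 55.8 ± 6.43 CPM (SD, n = 4; log2 fold change -1.75 ± 0.16 SE), tbx5b from 105 ± 20 to 11.4 ± 3.03 CPM (-3.2 ± 0.21) and srfb from 40.7 ± 6.5 to 9.89 ± 1.48 CPM. The 5 that rose were mef2cb (1.63 ± 0.15), tbx2a (2.31 ± 0.28), tbx3a (3.39 ± 0.37), irx3a (1.06 ± 0.27) and hand2 (0.47 ± 0.14). gata5 read 313 ± 51.5 and 286 ± 47 CPM and was not called, but was called higher with library totals (0.59).

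Genes linked to heart regeneration and injury were higher as a list, with 22 of 39 tested members higher and 6 lower (median 1.05; camera adjusted p = 0.0138; adjusted p = 0.378 with an estimated correlation; 0.234 with library totals; 0.0575 without genes shared with another list). The retinoic acid synthesis enzyme aldh1a2 rose from 82.2 ± 14.9 to 586 ± 65.7 CPM (SD, n = 4; log2 fold change 2.83 ± 0.17 SE), the metalloproteinase inhibitor timp2b by 4.57 ± 0.26 and the EGF-family ligand hbegfa by 2.24 ± 0.15. The natriuretic peptide gene nppa fell from 4620 ± 830 to 1260 ± 281 CPM (-1.87 ± 0.21), and the muscle desmin desma from 1990 ± 149 to 1070 ± 233 CPM (-0.89 ± 0.18). runx1, another member, was listed at 0 in all 8 libraries. Of 33 tested FGF, BMP and ErbB signalling genes, 19 were higher and 6 lower (median 0.55; camera adjusted p = 0.0195; adjusted p = 0.461 with an estimated correlation; 0.216 with library totals). bmp5 rose from 0.513 ± 0.317 CPM, close to the limit that a count of 0 allows, to 58.5 ± 21.5 CPM, so the size of its rise is imprecise. id3, a target of BMP signalling, rose by 2.77 ± 0.2. In contrast fgf3 (-2.39 ± 0.18), bmp10 (-1.59 ± 0.17) and dusp6, a target of FGF signalling (-1.02 ± 0.26), fell. Of 8 tested Hippo-Yap targets, 5 were higher and 2 lower (3 lower adjusted over the list alone; median 0.78; camera adjusted p = 0.258). ctgfa (3.47 ± 0.19), f3a (3.01 ± 0.24), amotl2b (1.39 ± 0.18), amotl2a (0.8 ± 0.15) and lats2 (0.76 ± 0.18) rose, and tgfb2 (-1.19 ± 0.14) and f3b (-0.93 ± 0.22) fell.

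Of 28 tested genes of the integrated stress and unfolded protein responses, 16 were higher and 7 lower (median 0.7; camera adjusted p = 0.0299; adjusted p = 0.378 with an estimated correlation; 0.234 with library totals). The chaperones and folding enzymes of the endoplasmic reticulum hsp90b1 (148 ± 17.4 to 478 ± 38.1 CPM, SD, n = 4), pdia4 (37.5 ± 1.9 to 120 ± 11.3 CPM) and creld2 (2.78 ± 0.416 to 16.2 ± 2.24 CPM) rose. The mitochondrial chaperone hspa9 fell from 699 ± 92.9 to 310 ± 65.6 CPM. Not called was atf4a, which encodes the factor at the centre of the integrated stress response, at 284 ± 13.8 and 337 ± 44.2 CPM. Of 36 tested ribosome biogenesis genes, 16 were higher and 4 lower (median 0.35; camera adjusted p = 0.179, or 0.0467 with library totals). The nucleolar methyltransferase fbl rose by 1.03 ± 0.13, and utp18 (-1.17 ± 0.14), nop14 (-0.77 ± 0.12), ddx21 (-0.66 ± 0.13) and bysl (-0.29 ± 0.1) were lower. With library totals ddx21 had the opposite sign, 0.06, and bysl was called higher (0.42, adjusted p = 0.00419 by edgeR). The call of bysl was lost without WT library 1 (adjusted p = 0.0616), WT library 4 (0.0751), klf1 library 3 (0.0661) or klf1 library 4 (0.0635), with upper-quartile factors (0.0989) and with no filter on low counts (0.0648).

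Markers of non-muscle cell types did not move together. Macrophage and granulocyte genes were higher, with 28 of 32 tested members up and 0 down (median 1.91; camera adjusted p = 2.25e-07; adjusted p = 0.275 with an estimated correlation). The leukocyte plastin lcp1 rose from 20 ± 4.16 to 132 ± 25.5 CPM (SD, n = 4; log2 fold change 2.72 ± 0.19 SE), coro1a by 2.67 ± 0.22, the macrophage growth factor receptor csf1ra from 29.7 ± 2.68 to 104 ± 18.8 CPM (1.81 ± 0.15) and the MHC class II chaperone cd74a by 1.49 ± 0.27. Fibroblast and extracellular matrix genes were higher in 22 of 29 cases and lower in 1 (median 1.05; camera adjusted p = 0.000144; adjusted p = 0.275 with an estimated correlation). Fibronectin fn1b rose from 405 ± 105 to 1280 ± 569 CPM, postnb by 2.12 ± 0.23, loxl2b, a collagen cross-linking enzyme, by 2.23 ± 0.16 and s100a10b by 1.93 ± 0.19. The 1 lower member, bgnb (-0.37 ± 0.14), had the opposite sign, 0.34, with library totals, and its call was lost without WT library 1 (adjusted p = 0.057), WT library 4 (0.0747), klf1 library 1 (0.0521), klf1 library 2 (0.0777) or both WT library 3 and klf1 library 1 (0.0529), and with upper-quartile factors (0.072).

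The epicardial list had 9 of 16 tested members higher and 3 lower (median 1.03; camera adjusted p = 0.0787, or 0.0496 without klf1 library 3 and 0.0149 with the stricter filter on counts, where the median was 1.77). The keratins krt4 (98.6 ± 25.5 to 1860 ± 391 CPM, SD, n = 4) and krt18 (181 ± 15.7 to 1150 ± 282 CPM) and the annexin anxa2a (614 ± 60.2 to 2510 ± 638 CPM) rose. hsd11b2, an enzyme that inactivates glucocorticoid hormone, fell from 1600 ± 157 to 205 ± 55.5 CPM and podxl from 1140 ± 166 to 461 ± 25.2 CPM. The other lower member, sema3d (-0.84 ± 0.32), lost its call without WT library 1 (adjusted p = 0.0931), 2 (0.105) or 4 (0.0653) or klf1 library 1 (0.0522) or 3 (0.0917), and with limma-voom (0.0692). Endocardial and endothelial genes were higher in 3 and lower in 10 of 25 cases (median -0.15, or 0.57 with library totals; camera adjusted p = 0.186). The receptor tek fell from 133 ± 9.11 to 48.9 ± 10.6 CPM and the adhesion molecule pecam1 from 47.2 ± 5.85 to 26.1 ± 3.53 CPM. The scavenger receptor stab2 rose from 8.3 ± 2.24 to 35.5 ± 6.01 CPM and the flow-responsive factor klf2b from 17 ± 2.53 to 31.6 ± 7.49 CPM. vwf, the clotting factor that endothelium secretes, was higher at 984 ± 254 and 1790 ± 618 CPM, a call lost without klf1 library 4 (log2 fold change 0.69, adjusted p = 0.0553). Smooth muscle and mural cell genes were higher in 3 and lower in 4 of 11 cases (median 0.2, mean -0.04, camera direction lower, adjusted p = 0.795). tagln (2.39 ± 0.32), kcne4 (1.8 ± 0.33) and rgs5b (1.72 ± 0.26) rose, and abcc9 (-2.62 ± 0.17), rgs5a (-2.07 ± 0.23), rgs4 (-1.55 ± 0.27) and tpm2 (-0.69 ± 0.18) were lower, with tpm2 at 0.02 under library totals. The smooth muscle actin acta2, at 103 ± 22.9 and 128 ± 21.9 CPM, was called higher only without WT library 1 (log2 fold change 0.45) and with library totals (1.03).

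Red blood cell genes, the textbook targets of Klf1, were not called higher as a list. Of 28 tested erythroid genes, 2 were higher and 13 lower (12 lower adjusted over the list alone; median -0.43; camera adjusted p = 0.0132; adjusted p = 0.399 with an estimated correlation). The median was 0.29 with library totals, where that of all tested genes was 0.75. The globin gene hbaa1 read 827 ± 280 CPM in WT and 739 ± 161 CPM in klf1 hearts (SD, n = 4; adjusted p = 0.596). Globin genes are near-identical copies, so single values are uncertain, and ba1 was listed at 0 in all 8 libraries. The 2 higher members were the heme synthesis genes hmbsb (log2 fold change 0.94 ± 0.17 SE) and urod (0.49 ± 0.13). The heme synthesis enzyme fech fell from 8.31 ± 0.323 to 2.49 ± 0.373 CPM and tspo, a protein of the outer mitochondrial membrane, from 114 ± 21.7 to 25.4 ± 2.02 CPM. Lymphocyte and thrombocyte genes were higher in 6 and lower in 1 of 11 cases (median 0.81; camera adjusted p = 0.186). cd4 rose from 1.43 ± 0.535 to 5.05 ± 1.14 CPM, and the platelet receptor subunit gp1bb changed by -0.64 ± 0.18, or 0.08 with library totals. Among 19 tested Krüppel-like and Sp factors, klf1 included, 7 were higher and 8 lower (median -0.23, or 0.48 with library totals; camera adjusted p = 0.795). klf12b (2.59 ± 0.18) and klf8 (1.95 ± 0.16) rose, and klf11b (-2.08 ± 0.21) and klf15 (-0.93 ± 0.13) fell.

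Of 24 tested genes of DNA methylation and histone modification, 10 were higher and 4 lower (median 0.18; camera adjusted p = 0.18). The maintenance DNA methyltransferase dnmt1 rose from 15.3 ± 2.03 to 92.4 ± 21.7 CPM (SD, n = 4; log2 fold change 2.59 ± 0.18 SE), its partner uhrf1 from 6.02 ± 0.923 to 66.6 ± 19.4 CPM (3.47 ± 0.22), the helicase hells by 4.56 ± 0.3 and dnmt3ba by 2.31 ± 0.19. smarcd3b (-1.43 ± 0.14), ezh1 (-1.18 ± 0.16), kdm6bb (-0.79 ± 0.18) and dnmt3ab (-0.69 ± 0.17) were lower, with dnmt3ab at 0.02 under library totals. Lists for tissues outside the heart had few tested members. Of 5 liver genes, cp (0.24 ± 0.167 to 12.9 ± 7.58 CPM, from below the limit that a count of 0 allows) and c3a.1 (1.92 ± 0.736 to 13.5 ± 8.99 CPM) rose and rbp4 (-1.61 ± 0.23) and ahsg1 (-1.58 ± 0.43) fell (median -0.2, or 0.5 with library totals; mean 1.02; camera direction lower, adjusted p = 0.982). tfa was not called, but was lower without klf1 library 1 (log2 fold change -0.57) and without both it and WT library 3 (-0.62). Of 7 nervous system genes, tubb5 (3.39 ± 0.22), plp1a (0.121 ± 0.0986 to 1.15 ± 0.435 CPM, likewise from below that limit) and snap25a (1 ± 0.29) rose and syt1a (-3.55 ± 0.73) and plp1b (-2.3 ± 0.36) fell, with syt1a at -5 without klf1 library 2 (list median 0.55, or -0.07 without klf1 library 4; camera adjusted p = 0.759).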

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

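For 368 sets of 4 values, the highest or lowest library was compared with the other 3. The sets were the library total and each gene drawn up for the text, in each genotype. Those genes leave out some that the naming rule allows and include some added after their values were seen. Of the 368 sets, 12 stood apart by Dixon's criterion at 95%, fewer than the 5% that chance gives. In WT library 3, fxyd1 read 918 CPM against 645 to 677 in the others, casq1b 406 against 303 to 313, and klf2b 13.3 against 18 to 18.8. In WT library 2, timp2b read 10.7 CPM against 15.8 to 17 and c3a.1 3.02 against 1.5 to 1.59. In WT library 4, dnmt1 read 18.4 CPM against 14.2 to 14.4, nop14 65.6 against 78.1 to 80.2 and plp1b 2.94 against 3.98 to 4.16. Among klf1 libraries, kdm6bb read 46.8 CPM in library 1 against 76.4 to 77.3, timp2b 210 in library 2 against 377 to 418, cpt1aa 18.4 in library 3 against 17 to 17.2, and hsp90b1 421 in library 4 against 493 to 500. No biological explanation was tested for these values.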

How the results depend on the processing

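Over 22 settings for genes and 16 for lists, the count of called genes stayed between 5229 and 8234 except under the test against a log2 fold change of 1, which was chosen after seeing the data. That stricter test called 1315 genes higher and 1130 lower, 2445 in all, by its own construction. With library totals 6836 genes were higher and 1398 lower, since that scaling sets the median gene at 0.75, and 4 lists were higher in place of 7. Of the 6461 called genes, 6315 were called in the same direction by DESeq2, which gave no adjusted p for 1058 genes, and 6384 by limma-voom. With a correlation estimated per list, camera called 0 lists higher, 0 lower and 0 in all (6 at an unadjusted p under 0.05), against 15 with the preset correlation and 22 with fry, which compares no list with other genes and called 14 higher. The estimated correlations reached 0.728 for oxidative phosphorylation. Leaving out a library gave 6016 to 6695 called genes, 15 to 16 lists, and a klf1 log2 fold change of 1.39 to 1.76. Leaving out WT library 3 and klf1 library 1 together, chosen after seeing that they lay apart on the second principal component (4.82% of the variance), gave 3535 higher and 3253 lower genes. Over the 182 genes besides klf1 that were drawn up for the text, 3880 values under other settings kept their side of the threshold. A further 93 lost the call, 14 gained one, and 10 changed sign in a gene called under the main or the other setting. Of the 93, 44 came with the test against a log2 fold change of 1 and 7 with the threshold of 0.01, which are stricter by construction. Changes of sign in genes called under neither were not counted apart and are among the 3880. All 10 of the counted changes of sign came with library totals and lie below the 0.75 shift of the median: cox8a 0.37, ccnf 0.72, gata5 0.59, sptb 0.27, dnmt3ab 0.02, bgnb 0.34, gp1bb 0.08, ddx21 0.06, bysl 0.42 and tpm2 0.02. The call of sptb was also lost without WT library 1, 2 or 4 or klf1 library 1, 3 or 4 (adjusted p = 0.0775 to 0.101), with upper-quartile factors (0.0733) and with no filter (0.055). With library totals cox8a, ccnf, gata5 and bysl were called higher. sva estimated 2 surrogate variables, of which 1 was used. No paired analysis was possible because the RNA preparation numbers run from 1 to 4 in WT and from 5 to 8 in klf1 hearts, so none is shared. In the simulation 73% of genes changed by log2 1 were recovered. Only 100 genes were changed by each size there, far fewer than were called here, so 73% is not the share found in this comparison. Some smaller changes may still have been missed with 4 libraries per group at this depth.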

Other observations

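Of the tests in this part, the counts over other splits of the libraries were planned before their result was seen, and all others were chosen after the gene lists had been read. Genes for the mitochondrial ribosome, which translates the genome of the organelle, were lower in klf1 hearts in 66 of 68 tested cases and higher in 0 (edgeR adjusted p under 0.05; median log2 fold change -1.3; camera adjusted p = 1.84e-17; adjusted p = 0.611 with an estimated correlation). mrps2 fell from 69.7 ± 4.22 to 20.7 ± 2.22 CPM (SD, n = 4) and mrpl15 from 108 ± 15.5 to 24.6 ± 5.06 CPM. Mitochondrial protein import genes were lower in 17 of 19 cases and higher in 0 (median -0.82; camera adjusted p = 0.0000882; adjusted p = 0.611 with an estimated correlation), with timm44 changed by -1.46 ± 0.15 (SE). The symbol left out of this list after its value was seen, tomm34, was higher (0.55 ± 0.17). With it, 17 of 20 were lower and 1 higher (median -0.81; camera adjusted p = 0.000226). Ribosomal proteins of the cytosol stayed apart from this: of 79 tested, 4 were higher and 2 lower (median 0.09; camera adjusted p = 0.476).

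DNA repair and checkpoint genes were higher in 24 of 30 cases and lower in 0 (median 1.22; camera adjusted p = 9.01e-07; adjusted p = 0.611 with an estimated correlation). fancd2 rose from 3.14 ± 0.287 to 27.3 ± 4.12 CPM (SD, n = 4) and the exonuclease exo1 from 0.366 ± 0.112 to 7.64 ± 2.09 CPM. The WT value of exo1 is close to the limit that a count of 0 allows, so the size of its rise is imprecise. Of 39 proteasome subunits 31 were higher and 0 lower (median 0.6; camera adjusted p = 0.0000882; adjusted p = 0.611 with an estimated correlation), psmd11a among them at 0.91 ± 0.12 (SE). The immune-type subunits psmb9a (2.14 ± 0.27), psmb8a (1.47 ± 0.27), psmb12 (1.35 ± 0.27) and psmb10 (1.3 ± 0.34) rose most, as macrophage and granulocyte markers also rose (median 1.91), and the first 2 are also in the interferon list. The remaining symbol-pattern lists were not called: interferon response 10 higher and 2 lower of 27 (median 0.69), spliceosome 16 and 3 of 44 (0.15), vacuolar ATPase 10 and 3 of 19 (0.34), collagens 8 and 2 of 14 (0.77), keratins 5 and 1 of 8 (1.09), cholesterol synthesis and its regulation 6 and 3 of 20 (0.3), claudins 4 and 1 of 10 (0.47), and the TCP1 chaperonin 0 and 3 of 7 (-0.26). Before symbols were left out, with their values known, the interferon list had 11 higher and 5 lower of 31 (median 0.51) and the spliceosome list 17 and 5 of 49 (0.07). Collagens then had 8 and 2 of 15 (0.53), claudins 4 and 1 of 11 (0.39) and proteasome subunits 33 and 0 of 42 (0.58). Keratins and collagens share members with lists read earlier.

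The fall of cardiac muscle genes was set against 2 explanations. A lower share of cardiomyocytes as the whole cause would raise markers of every other cell type alike. Instead, the macrophage median lay 2.05 above the endothelial median. An exact permutation over the 8 libraries gave p = 0.0286, the smallest that 4 against 4 can give. Here and in later permutations of list gaps, the permuted value was the gap per library between list medians of centred log2 CPM. The pair was chosen after its medians were known, so this p-value is not independent support. A fall of cardiomyocyte share together with an influx of macrophages would lower transcripts made only in cardiomyocytes by 1 common factor. Sarcomere members instead ran from -7.38 to 0.02 (median -2.27), with lmod2a at -7.38 ± 0.55, myl7 at -3.94 ± 0.31 and vmhcl at -2.48 ± 0.24 (SE). This argues against it as the whole cause, as far as these transcripts come from cardiomyocytes alone, which was not tested. As part of the cause it stays open. Scaling by a few very abundant genes is argued against by the sarcomere median, which was at most -1.56 over 4 scalings. Whether klf1 overexpression itself brought about the fall was not tested, since the labels give no batch that could be separated from genotype. The labels do not say in which cells klf1 was overexpressed, and whole-heart counts do not separate a change within cardiomyocytes from a change in cell make-up.

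The rise of the cell cycle list was set against 2 further explanations. More leukocytes, each cycling as in WT hearts, would raise it by no more than the leukocyte markers, yet its median lay 2.24 above the macrophage and granulocyte median (exact permutation of the gap per library, p = 0.0286, the smallest possible). This pair, too, was chosen after its medians were known, and the p-value belongs to the permuted gap, not to the 2.24. Over 4 scalings the cell cycle median was at least 4.12. Which cells cycled cannot be told apart, since the list median of 4.15 comes from whole hearts and ties no transcript to a cell type. Cycling cardiomyocytes, cycling macrophages or fibroblasts, or both may contribute.

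A hypothesis that all nuclear genes for mitochondrial proteins fell by the same amount was not borne out: the mitochondrial ribosomal median lay 0.86 above that of oxidative phosphorylation (exact permutation of the gap per library, p = 0.0286, the smallest possible). It was set after both medians were known, so the p-value is not independent support. A hypothesis that raised klf1 raises erythroid genes as a set in these hearts, relative to other genes, was not borne out by any set test. The erythroid median minus that of all tested genes was -0.46, a difference that scaling leaves almost fixed, and 2 of 28 tested members were higher and 13 lower. The list was called lower by camera with the preset correlation (adjusted p = 0.0132) and by fry (adjusted p = 0.00141). With an estimated correlation the camera adjusted p was 0.399, so whether the list fell as a set could not be decided.

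Among the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave 6461 called genes. The highest of the others gave 0 by edgeR, with at most 1174 at an unadjusted p under 0.05. The real split thus ranked first for the count of genes, and its share, 1 of 35, is the smallest this design can give. A chance assignment of these libraries is argued against only as far as that share goes. The other splits mix the genotypes, which adds the genotype difference to their spread, so their 0 does not estimate how many calls are false. For lists the splits do not set the real grouping apart: 4 of the 35 splits, the real one included, gave 15 or more called lists, and the highest other gave 17. The 3 others set 3 klf1 libraries and 1 WT library against the rest, and thus keep part of the genotype difference, but the 18 splits with both genotypes balanced also gave up to 12 called lists (median 4). The balanced splits, too, carry the genotype difference in their spread. Their list counts therefore cannot tell whether the preset correlation of 0.01 is too low for the real grouping. The correlations estimated per list, which rest on 8 libraries, ran from -0.011 for serine, one-carbon and amino acid synthesis to 0.728 for oxidative phosphorylation. Every list called with the preset, apart from the serine list, had an estimate of 0.1 or more. For those lists the estimates argue that 0.01 is too low and that p-values with the preset are too small. In the main fit camera called 15 lists with the preset correlation and 0 with an estimated correlation. Other settings went above 15, with 17 lists under the stricter filter on counts and 22 by fry.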
